A study of Homo sapiens with 4 samples.

How the data were processed

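Gene-level RNA-seq counts were analysed for 4 libraries of H9 human embryonic stem cells at day 7, 2 wild-type (WT) and 2 with the genotype label TFAP2A knockout. Per the labels' protocols, RNA was taken up in TRIzol, cleaned on RNeasy columns with DNase treatment, and made into libraries with a KAPA kit for polyA-enriched mRNA. No growth protocol, clone or guide is given in the labels used here. Groups were taken from the genotype label, because the sample titles of the knockout libraries name TFAP2C while the genotype label, the series title and the column names of the table name TFAP2A.

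The authors deposited a single table of 25690 gene rows with estimated counts per gene. Per the submitters' processing notes the tools were TopHat, HOMER and DESeq2 and the build hg38, with no versions. The annotation and the use of strand are not given in the sources used here, nor are the full counting settings. All values were multiples of 0.5 and 37.0% of them were not whole numbers, for a reason that the sources used here do not give. They were rounded to whole numbers for the count models. Gene positions in the table did not match hg38. Of 22707 genes found in a GRCh38 annotation, only 4.38% began within 2000 bp of their GRCh38 position, and 42 rows were on contigs named as in hg19, so coordinates are printed as hg19. A spreadsheet had turned 28 symbols into dates, and these genes were not named. Another 3 symbols occurred in more than 1 row, and 4531 genes had 0 counts in all libraries.

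Total counts per library were 17945210 and 17838204 in WT and 19305868 and 21797850 in the libraries labelled knockout, and the 10 most abundant genes took 4.02% to 4.34% of them. At this depth 3 counts, the limit that a count of 0 allows, correspond to 0.138 to 0.168 CPM per library. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 4.32 in WT and 4.17 in the libraries labelled knockout. The common biological coefficient of variation was 0.0577, with 2 residual degrees of freedom. PCR duplicates cannot be told from independent molecules in counts per gene.

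Genes were filtered with filterByExpr, which left 15643, and scaled with TMM factors. They were tested with edgeR 4.0.16 (glmQLFit with robust estimation and glmQLFTest) on genotype alone, in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use the TMM-adjusted library sizes. The standard error of a log2 fold change was computed as its size over the square root of the F statistic. Ratios with 1 to 3 counts in a group have 95% exact (Clopper-Pearson) counting intervals. A fold against 0 counts was computed against 3 counts over the group and is a lower bound.

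Gene lists were fixed before the data were examined. There were 21 with 409 symbols, of which 407 were found, 3 by an older symbol. They held the TFAP2 family, surface ectoderm transcription factors, simple epithelial keratins and adhesion, basal keratinocyte and hemidesmosome, desmosome, keratinocyte differentiation, neural ectoderm, neural crest, cranial placode, pluripotency, mesoderm and endoderm, mesenchyme and extracellular matrix, endothelium and blood, amnion and trophoblast, BMP, WNT and retinoic acid response, cell cycle, p53 and stress response, interferon response, and mitochondrial respiratory and ribosomal protein genes. The other 20 were tested against the remaining genes with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over these 20, with an estimated correlation and with fry as alternatives. All camera calls at the preset correlation were lost with an estimated correlation.

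Named genes followed a rule also written before the data were examined. It took the TFAP2 family and the 10 protein-coding genes with the largest rise and the 10 with the largest fall among genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap between genotypes. It added up to 4 members of each list with the largest change, or the 2 members with the highest mean CPM where fewer than 2 passed. Other genes named were chosen after their values were seen. Gene types came from NCBI RefSeq, which covered 97.6% of the genes tested, by symbol or synonym.

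Genes of each chromosome were tested with camera in the same way. The table does not give chromosome arms, so whole chromosomes were used where arms had been planned. The stretch scan was added after seeing the data. It took 11979 genes with a mean of at least 5 CPM in genome order, limited log2 fold changes to between -1 and 1, and found on each chromosome the run with the highest summed excess over the midpoint between 0 and the log2 of 1.5 (or, for lower runs, between 0 and -1). Scores were compared with 1000 shuffles of the gene order. GC content and transcript length came from the longest GENCODE transcript of each symbol, found for 96.6% of the genes tested.

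The gene test was tested on simulated counts with the WT means, the fitted dispersions and the library sizes of these samples (15467 genes fitted). It recovered 66 of 100 genes changed 1.5-fold and 85 of 98 changed 2-fold, and 18 of its 169 calls were unchanged genes, above the nominal 5%. In simulated data camera called the shifted list and 0 other lists, and the scan found 150 of 150 raised genes and 0 others. Each gene was drawn independently and all other genes were left unchanged, whereas 44.2% of genes changed in the data. These simulations therefore do not cover correlation between genes or a stretch set among other changes.

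Alternatives fixed before the data were examined were RLE and upper-quartile factors, no low-count filter, a filter of 1 CPM in at least 2 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, thinning to the smallest library, and a minimum log2 fold change of 1. Unrounded counts, leaving out the genes of the chromosome 1 and X stretches, and removal of the GC trend were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.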

Results

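RNA was measured by polyA-selected RNA sequencing in H9 cells, a human embryonic stem cell line, collected at day 7. The series describes the cells as non-neural ectoderm, the part of the early ectoderm from which epidermis, cranial placodes and neural crest arise. It compares wild-type (WT) cells with cells whose genotype label reads TFAP2A knockout, with 2 libraries of each. The libraries held 17945210 and 17838204 counts in WT, and 19305868 and 21797850 counts in the libraries labelled knockout. Nothing in the labels says that the libraries of a genotype came from separate cultures, so each p-value measures the spread between these libraries, which may be technical. The sample titles of the knockout libraries name TFAP2C, whereas the genotype label and the series title name TFAP2A. Levels are CPM, counts scaled to the size of each library, given as mean ± SD over 2 libraries. Adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 15643 genes tested.

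All of the 4 TFAP2 family genes with enough counts to test were lower in the libraries labelled knockout. These genes encode AP-2 transcription factors of the ectoderm, neural crest and trophoblast. TFAP2A (chromosome 6, 10396916 to 10412607, minus strand, hg19) kept most of its transcript, at 171 and 198 CPM in the WT libraries against 133 and 121 CPM in those labelled knockout, a log2 fold change of -0.54 (SE 0.07, adjusted p = 0.000125). TFAP2B on the same chromosome showed the largest fall of the family, from 274 ± 18.3 to 43.1 ± 3.66 CPM, 6.36-fold lower (log2 fold change -2.67, SE 0.07, adjusted p = 8.65e-12). TFAP2C (chromosome 20, 55204358 to 55214338, hg19), the gene in the sample titles, fell from 29.04 ± 2.16 to 7.34 ± 2.22 CPM (log2 fold change -1.99, SE 0.17, adjusted p = 6.66e-06) and was not at 0 in either library. TFAP2E fell from 11.5 ± 0.193 to 6.49 ± 0.748 CPM (adjusted p = 0.00033). TFAP2D had 0 counts in all 4 libraries, which allows up to 0.138 to 0.168 CPM per library (3 counts). TFAP2A-AS1, a non-coding gene whose ends overlap TFAP2A, was at 6.53 ± 0.546 CPM against 3.86 ± 0.241 in WT, but whether the counting used strand is not given in the sources used here, so reads from that overlap, a small part of either gene, cannot be assigned. Counts per gene do not show which exons the remaining TFAP2A reads came from. They therefore check the genotype label only in part, and a direction below is that of the libraries labelled knockout.

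**Figure D1:**
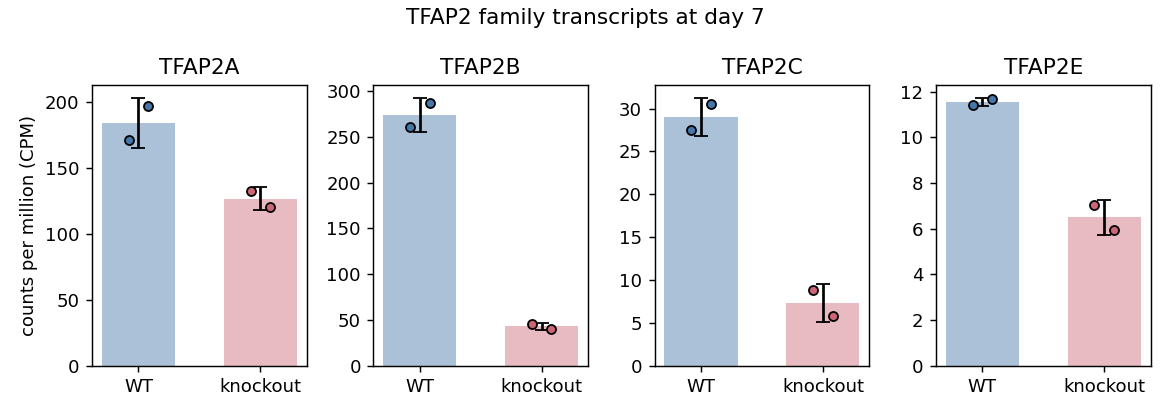
CPM of 4 TFAP2 family genes (vertical axes, each from 0) in WT and labelled knockout libraries. Points are libraries, bars are means and error bars are SD (n = 2 per genotype). TFAP2B shows the largest relative fall (274 to 43.1 CPM) and TFAP2A the smallest, with all 4 points above 120 CPM.

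Among the 15643 genes tested, 3427 were higher and 3492 were lower in the libraries labelled knockout, and 8724 did not pass (44.2% changed). With a log2 fold change of at least 1 also required, 703 were higher and 1059 lower.

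The 10 protein-coding genes with the largest rises included PNOC, the precursor of the neuropeptide nociceptin, FGF5, a fibroblast growth factor of the epiblast, and LHX1, a LIM-homeodomain transcription factor. PNOC was at 15.2 ± 5.499 CPM against 0.028 ± 0.0395 in WT, where it had 1 count, a ratio of 538 (95% counting interval 96.2 to 21284). FGF5 reached 7.57 ± 0.125 CPM against 2 counts in WT, a ratio of 136 (37.4 to 1130). LHX1 reached 8.35 ± 0.792 CPM against 2.5 counts, a ratio of 120 (33.9 to 486), and the zinc finger gene ZNF502 reached 5.47 ± 0.668 CPM against 3 counts, a ratio of 65.3 (22.1 to 319). ZC3HAV1L, ZXDA, PNPLA4, STAC, TSPYL5 and CTSF made up the rest. Of these, TSPYL5 had the highest level, 34.4 ± 1.71 CPM against 0.872 ± 0.111.

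The 10 largest falls by fitted fold change included THNSL2 and C9orf64, neither of which had a count in the libraries labelled knockout, so their folds are lower bounds and their order is not established. THNSL2 was at 18.4 ± 0.177 CPM in WT, at least 251-fold higher than the 3 counts over the group that a count of 0 allows, and C9orf64 was at 11.8 ± 0.799 CPM, at least 161-fold higher. PXMP4, which encodes a peroxisomal membrane protein, had 1 count against 10.8 ± 1.33 CPM, a ratio of 441 (78.7 to 17467). LMX1B, a LIM-homeodomain factor of limb and neural patterning, fell from 85.03 ± 11.3 to 1.40 ± 0.0418 CPM (log2 fold change -5.91, SE 0.14). EDNRB, the endothelin receptor of neural crest cells, fell from 39.7 ± 3.93 to 0.685 ± 0.191 CPM. IRX4, an Iroquois homeobox factor, fell from 8.36 ± 0.0371 to 0.102 ± 0.145 CPM. RHBDL3, ANKRD63, TNFSF8 and CCDC125 completed this group. Intervals and floors cover counting error only.

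**Figure D2:**
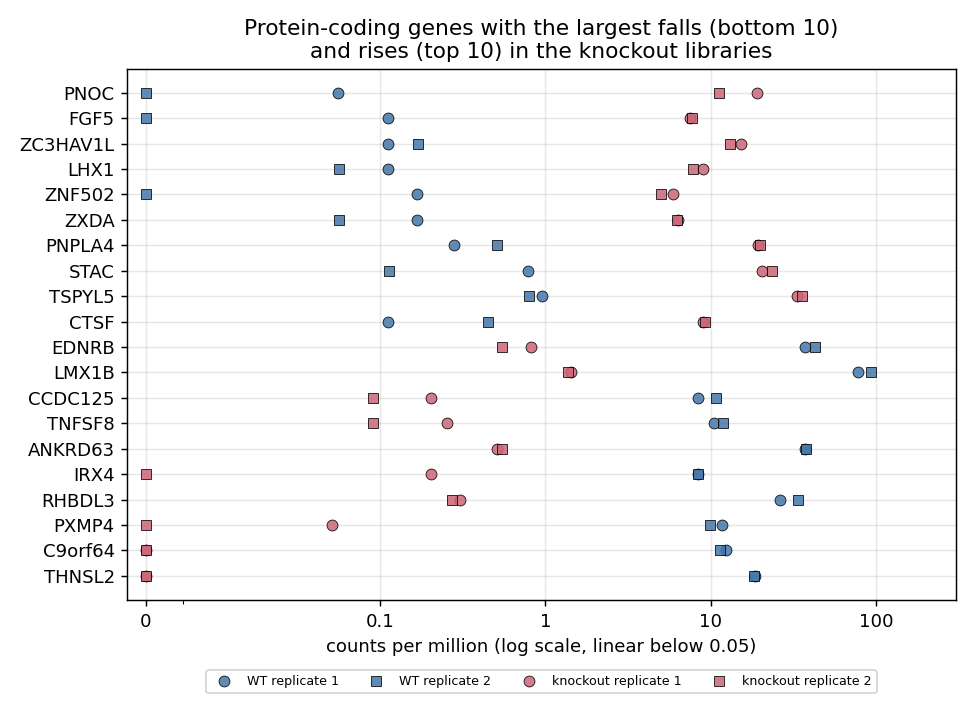
CPM (horizontal, log scale, linear below 0.05) of the 10 protein-coding genes with the largest rises (top) and the 10 with the largest falls (bottom), with a point for each of the 4 libraries. No overlap between the genotypes was a condition for choosing these genes. THNSL2 and C9orf64 lie at 0 in both libraries labelled knockout.

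Transcription factors of the surface ectoderm were lower as a group. Of 21 tested, 14 fell, 0 rose and 7 did not pass, and the counts adjusted over the list alone were the same (median log2 fold change -0.49; camera, adjusted p = 6.55e-15). With an estimated correlation the adjusted p was 0.292. MSX1, a BMP-responsive homeobox factor, fell from 103 ± 16.1 to 8.14 ± 0.285 CPM, and GRHL1, a grainyhead factor of epithelial differentiation, from 56.7 ± 3.42 to 10.3 ± 1.15 CPM. KLF4 fell from 7.92 ± 1.47 to 1.48 ± 0.219 CPM. The epidermal regulator TP63 did not pass, at 18.5 CPM against 22.9 in WT, nor did TBX3, at 383 against 386 CPM.

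Genes of simple epithelia fell with them. Of 22 keratins, claudins and other adhesion genes, 15 fell (16 adjusted over the list alone) and 2 rose (camera, adjusted p = 1.27e-06; median log2 fold change -0.33). The adjusted p was 0.437 with an estimated correlation. The matriptase gene ST14 fell from 61.8 ± 3.56 to 15.2 ± 3.11 CPM, PROM2 from 86.8 ± 6.03 to 24.96 ± 1.21 and the keratin gene KRT7 from 227 ± 28.1 to 67.7 ± 5.31. Those that rose were CLDN10, from 2.54 to 6.33 CPM, and MAL2, from 41.2 to 49.6, the latter with an adjusted p of 0.051 without knockout replicate 1 and also lost when the GC trend was removed. Where 5 or fewer members of a list moved one way they are all named, except among those of the basal keratinocyte list that fell, and those outside the fixed rule for named genes, such as MAL2, were chosen after their values were seen.

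Desmosome genes moved both ways. Of 8 tested, 4 fell and 2 rose, with the same counts adjusted over the list alone (median log2 fold change -0.37; camera, adjusted p = 0.0096, and adjusted p = 0.336 with an estimated correlation). DSC3 fell from 42.8 ± 1.45 to 8.85 ± 0.523 CPM, PKP3 from 81.5 ± 2.46 to 21.7 ± 2.73 and PKP2 from 227 ± 1.86 to 126 ± 15.1. JUP also passed narrowly, at 492 against 538 CPM, but lost its call in 10 of 15 alternatives, among them DESeq2, both other scaling factors and leaving out WT replicate 2 (adjusted p = 0.191). DSP, the desmoplakin gene that anchors keratin filaments, rose from 2422 ± 124 to 3289 ± 157 CPM, and DSC2 rose from 211 to 249 CPM, a call lost when the GC trend was removed. The list's call was lost without the low-count filter (adjusted p = 0.299) and with limma-voom (0.273).

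Basal keratinocyte and hemidesmosome genes did not pass as a list (camera, adjusted p = 0.284; median log2 fold change -0.49). Of 10 tested, 5 fell (6 adjusted over the list alone), 2 rose and 3 did not pass. Among those that fell, the laminin chain gene LAMA3 went from 3.80 ± 0.316 to 1.34 ± 0.208 CPM. LAMB3, another laminin chain gene, which lies inside the chromosome 1 stretch described last, fell to 0.097 ± 0.00761 from 1.13 ± 0.0111 CPM. PERP fell from 142 to 86.7 CPM. COL17A1 was lower too, but its adjusted p was 0.13 without knockout replicate 2 and 0.101 without WT replicate 1, and the call was lost with DESeq2. ITGA3 and COL7A1 rose, with adjusted p of 0.212 without WT replicate 2 and 0.146 without WT replicate 1, and each was lost in 3 of 15 alternatives. Only 2 of 16 keratinocyte differentiation genes could be tested, and this list did not pass (adjusted p = 0.0976). The transglutaminase gene TGM1 fell from 10.5 ± 0.0241 to 1.35 ± 0.0306 CPM, while KRT10 was at 17.3 against 18.4 CPM and did not pass, and these calls were the same adjusted over the list alone.

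Neural ectoderm genes did not shift as a list (camera, adjusted p = 0.828; median log2 fold change 0.48), but 8 of 16 rose and 4 fell, also when adjusted over the list alone. SOX3, a SOXB1 factor of neural progenitors that lies inside the X stretch described last, rose from 1.75 ± 0.0172 to 6.76 ± 1.01 CPM. SOX1 was at 0.984 ± 0.419 CPM against 2 counts in WT, a ratio of 17.4 (4.52 to 149). SOX2 was at 41.6 ± 14.4 against 11.3 ± 0.526 CPM, a call lost without WT replicate 1 (adjusted p = 0.114) or 2 (0.248), without the low-count filter and with limma-voom. PAX6 rose from 2.48 to 6.52 CPM and the neural cadherin gene CDH2 from 111 to 256 CPM. The 4 that fell were DLK1, from 2109 ± 183 to 576 ± 72.0 CPM, POU3F1, from 4.47 ± 1.51 to 0.536 ± 0.11 CPM, NCAM1, from 195 to 91.7 CPM, and NES, from 259 to 135 CPM.

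Neural crest genes fell as a group. Of 12 tested, 6 fell (7 adjusted over the list alone), 0 rose and 6 did not pass (camera, adjusted p = 0.000237; median log2 fold change -0.75). The adjusted p was 0.268 with an estimated correlation. PAX7 fell from 4.36 ± 0.952 to 0.491 ± 0.175 CPM, RXRG from 9.34 ± 1.82 to 4.20 ± 1.01 and the neurotrophin receptor gene NGFR from 6.27 ± 0.774 to 2.82 ± 0.427. TFAP2B is in this list and in that of the surface ectoderm.

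Cranial placode genes split, with 4 of 10 lower and 3 higher, the same when adjusted over the list alone, and did not pass as a list (camera, adjusted p = 0.461; median log2 fold change -0.28). EYA2 fell from 31.8 ± 5.29 to 3.13 ± 0.143 CPM and EYA1 from 97.9 to 29.2 CPM; both encode transcriptional coactivators. FOXE3, a lens factor, fell from 3.21 ± 0.526 to 0.551 ± 0.128 CPM and FOXI3 from 4.90 to 1.20 CPM. GBX2 rose from 0.0843 ± 0.039 to 3.84 ± 1.16 CPM, PAX2, a factor of the ear and midbrain-hindbrain boundary, from 0.874 ± 0.208 to 7.06 ± 0.13, and DACH1 from 68.3 to 101 CPM.

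Pluripotency genes did not shift as a list (camera, adjusted p = 0.828; median log2 fold change 0.00). Of 10 tested, 7 did not pass, among them POU5F1 at 0.743 against 0.731 CPM in WT. SOX2, also in the neural list and with the losses given there, and ZSCAN10 (1.04 ± 0.13 to 2.76 ± 0.148 CPM) were higher, and LIN28A fell from 565 ± 36.8 to 370 ± 38.7 CPM. Adjusted over the list alone, 1 was higher and 1 lower.

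Several groups of genes of cell types outside the ectoderm differed, and most of these were lower. Among 25 genes of mesenchyme and extracellular matrix, 16 fell, 2 rose and 7 did not pass, the same counts adjusted over the list alone (camera, adjusted p = 2.47e-11; median log2 fold change -0.45). With an estimated correlation the adjusted p was 0.268. PRRX1, a factor of limb and craniofacial mesenchyme, fell from 40.4 ± 4.62 to 6.86 ± 0.283 CPM, the matricellular gene POSTN from 79.9 ± 3.51 to 14.6 ± 1.46, and COL6A3 from 282 ± 28.0 to 56.5 ± 3.06. The fibrillar collagen gene COL1A1 was at 2883 against 3096 CPM and did not pass. VIM rose from 776 to 1035 CPM, and LUM was at 75.5 against 58.8 CPM with an adjusted p of 0.249 without knockout replicate 2, lost in 5 of 15 alternatives.

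Amnion and trophoblast genes showed the lowest median of the lists, -2.92. Of 10 tested, 7 fell and 2 rose, the same counts adjusted over the list alone (camera, adjusted p = 4.17e-10, and adjusted p = 0.268 with an estimated correlation). VTCN1 fell from 348 ± 6.50 to 17.5 ± 3.43 CPM and the aromatase gene CYP19A1 from 2.76 ± 0.266 to 0.146 ± 0.0114. GABRP was at 62.6 ± 22.1 against 1167 ± 57.5 CPM, a call lost without WT replicate 1 (adjusted p = 0.0879) or 2 (0.124). CGA, which encodes the common alpha subunit of the glycoprotein hormones, had 0 counts against 2.09 ± 0.897 CPM in WT, at least 28.5-fold lower. With CGA at that bound the list's median was the same. ISL1 rose from 3.44 to 11.3 CPM, and PGF was at 12.5 against 8.95 CPM with an adjusted p of 0.179 without knockout replicate 1, and was lost with DESeq2 and without WT replicate 1 too.

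Among 7 genes of endothelium and blood, 5 fell and 1 rose, also when adjusted over the list alone (camera, adjusted p = 0.00217; median log2 fold change -2.55). The adjusted p was 0.292 with an estimated correlation. CDH5, the endothelial cadherin gene, fell from 11.9 ± 1.27 to 0.452 ± 0.204 CPM, RUNX1 from 4.11 ± 0.439 to 0.26 ± 0.151, the VEGF receptor gene KDR from 16.4 ± 0.117 to 2.26 ± 0.883 and the embryonic globin gene HBE1 from 14.2 ± 0.578 to 2.42 ± 0.122. EGFL7 fell from 8.81 to 5.95 CPM, a call lost with DESeq2. FLT1, another VEGF receptor gene, rose from 2.31 to 11.9 CPM.

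Mesoderm and endoderm genes did not shift as a list (camera, adjusted p = 0.923; median log2 fold change -0.42). Of 14 tested, 5 fell, 2 rose (3 adjusted over the list alone) and 7 did not pass. GATA4 rose from 96.6 ± 14.2 to 208 ± 15.7 CPM and HAND2 from 82.0 to 111, while GATA6 fell from 161 to 94.1 CPM. TBX6 fell from 2.79 ± 0.172 to 1.11 ± 0.0189 CPM and AFP from 0.985 ± 0.11 to 0.163 ± 0.158. MEOX1 and NKX2-5 were lower as well, with adjusted p of 0.106 and 0.0893 without knockout replicate 2, and both were lost with DESeq2 and without WT replicate 1 too.

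WNT response genes fell almost throughout. Of 13 tested, 12 fell (13 adjusted over the list alone) and 0 rose, with a median log2 fold change of -1.57 (camera, adjusted p = 6.55e-15). The adjusted p was 0.268 with an estimated correlation. The caudal homeobox gene CDX2 fell from 3.49 ± 0.194 to 0.123 ± 0.0438 CPM and CDX1 from 4.65 ± 0.165 to 0.394 ± 0.168. DKK1, which encodes a secreted WNT antagonist, fell from 13.2 ± 2.50 to 1.18 ± 0.366 CPM. SP5 was at 0.789 ± 0.167 CPM in WT against 1 count, a ratio of 31.6 (5.32 to 1315). NKD2, at 6.50 against 8.33 CPM, was the member that did not pass over all genes.

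BMP response genes did not move one way (camera, adjusted p = 0.3). Of 17 tested, 7 fell and 5 rose (8 rose adjusted over the list alone), with a median log2 fold change of 0.08 while the mean and the test pointed down. MSX1 and the ligand gene BMP4, from 69.5 ± 5.38 to 23.4 ± 1.56 CPM, fell. The inhibitor of DNA binding genes ID4 (74.96 ± 3.04 to 183 ± 0.397 CPM), ID3 (222 to 367 CPM) and ID2 (212 to 266 CPM) rose, as did NOG (7.26 to 12.5 CPM). BMP2 was at 2.86 against 1.21 CPM, with an adjusted p of 0.0688 without knockout replicate 1 and 0.058 without WT replicate 2.

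Retinoic acid response genes also split, with 11 of 22 lower and 7 higher, the same when adjusted over the list alone (camera, adjusted p = 0.196; median log2 fold change -0.10). CYP26A1, which encodes an enzyme that degrades retinoic acid, fell from 82.3 ± 4.33 to 10.1 ± 2.64 CPM. The receptor gene RARB fell from 86.1 ± 0.45 to 34.7 ± 2.28 CPM and the retinol carrier receptor gene STRA6 from 189 ± 9.18 to 76.2 ± 1.45. CRABP1 was at 48.3 ± 16.5 against 3.94 ± 0.0408 CPM, a call lost without WT replicate 1 (adjusted p = 0.0547) or 2 (0.149) and with limma-voom.

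Cell cycle genes rose by a small amount. Of 27 tested, 21 rose and 1 fell, also when adjusted over the list alone (camera, adjusted p = 0.00012; median log2 fold change 0.27). The adjusted p was 0.39 with an estimated correlation. TOP2A rose from 410 ± 21.9 to 587 ± 52.3 CPM, the kinesin gene KIF11 from 90.1 ± 5.40 to 126 ± 5.46 and the mitotic kinase gene BUB1 from 86.8 ± 2.81 to 119 ± 2.21. CENPF rose more, from 189 ± 18.9 to 517 ± 32.0 CPM, and lies inside the chromosome 1 stretch described last. Without the genes of that stretch and the X stretch, 20 of 26 rose (adjusted p = 0.000487). CCNE1 fell, from 33.9 to 25.7 CPM.

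The remaining lists did not pass. Among 22 p53 and stress response genes, 6 fell, 3 rose and 13 did not pass, the same when adjusted over the list alone (camera, adjusted p = 0.828), with a median log2 fold change of 0.01 and a mean of -0.08. HMOX1 fell from 19.9 ± 1.87 to 4.93 ± 0.421 CPM and BBC3 rose from 12.4 ± 0.874 to 19.7 ± 0.722. The others that rose, TRIB3 and ATF3, had adjusted p of 0.188 without knockout replicate 1 and 0.0966 without WT replicate 2 and were both lost with DESeq2, and ATF3 lies inside the chromosome 1 stretch. Among 17 interferon response genes 7 rose and 4 fell, also when adjusted over the list alone (camera, adjusted p = 0.828; median 0.00). OAS3 rose from 0.789 ± 0.167 to 2.40 ± 0.496 CPM. The peptide transporter gene TAP1 fell from 3.49 ± 0.671 to 0.776 ± 0.0609 CPM, HLA-B from 2.65 ± 0.345 to 0.814 ± 0.21, HLA-C from 151 to 88.7 and IRF7 from 13.4 to 6.68, although HLA genes share reads with each other. Of 25 mitochondrial respiratory and ribosomal protein genes, 5 fell, 2 rose and 18 did not pass (camera, adjusted p = 0.746; median -0.12). Adjusted over the list alone, 3 fell and 1 rose. RPL11 was at 526 ± 12.5 against 606 ± 17.997 CPM. Every other call in this list, for RPLP1, RPS12, RPLP0, RPL30, UQCRQ and ATP5G1, had an adjusted p between 0.083 and 0.286 on leaving out the library that weakened it most.

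**Figure D3:**
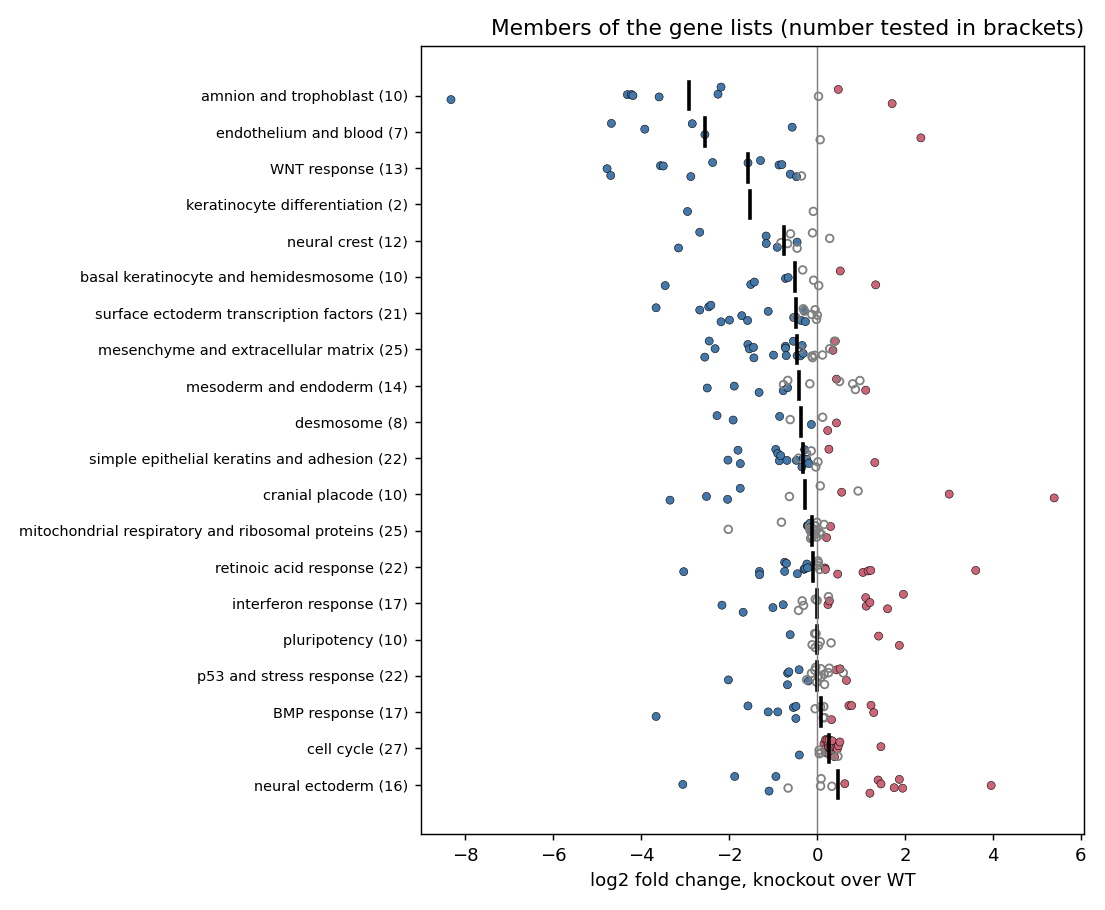
Log2 fold change, labelled knockout over WT (horizontal), of the members of 20 gene lists (rows, number tested in brackets). Filled points passed the test (red higher, blue lower), open points did not, and black bars mark medians, from -2.92 for amnion and trophoblast to 0.48 for neural ectoderm.

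As a check of the cell line, fold changes were compared along the chromosomes. Tested whole, 0 of 23 chromosomes passed (camera, lowest adjusted p = 0.884), with 0 at an unadjusted p under 0.05, or 1 with an estimated correlation. A scan for runs of neighbouring genes, chosen after seeing the data, found that genes at the far end of chromosome 1 were higher in the libraries labelled knockout. Between 196194910 and 247242115 (hg19, KCNT2 to ZNF670), the 228 genes with a mean of at least 5 CPM had a median log2 fold change of 0.62, or 1.53-fold (interquartile range 0.40 to 0.82). Of these, 203 lay above 0, 184 passed as higher and 14 as lower. The median was 0.62 in knockout replicate 1 and 0.61 in replicate 2. In 0 of 1000 shuffles of the gene order did any run score as high.

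A run on X from 122734412 to 144907360 (THOC2 to SLITRK2, 51 genes) had the same median of 0.62 with a wider interquartile range, -0.06 to 1.10, and 32 genes higher against 7 lower. It too was matched in 0 of 1000 shuffles. In all, 8 runs were matched in under 5% of the shuffles, 4 higher and 4 lower. The other 6 were short, the longest with 22 genes, and the 4 lower runs lay on chromosomes 2, 7 and 9 and on X. The run on chromosome 7 (MTURN to AQP1, 10 genes, all lower, median -1.18) was also matched in 0 of 1000 shuffles. The lower run on X (MXRA5 to STS, 6 genes, median -1.47) was matched in 3, that on chromosome 9 in 22 and that on chromosome 2 in 35. The listed genes ELF3, LAMB3, CENPF, ATF3 and MIXL1 lie inside the chromosome 1 stretch and SOX3 inside that on X.

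**Figure D4:**
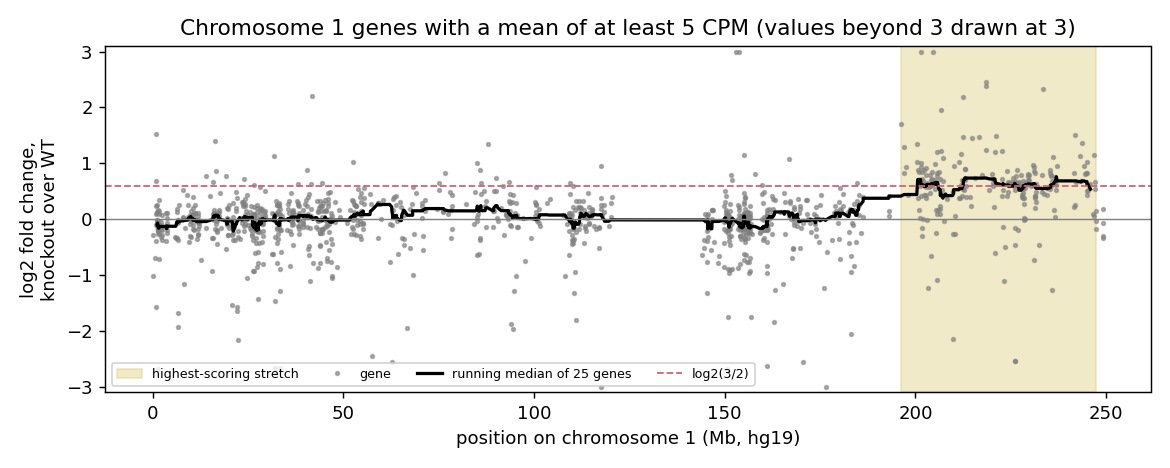
Log2 fold change, labelled knockout over WT (vertical), of chromosome 1 genes with a mean of at least 5 CPM by position in Mb (horizontal, hg19), with a running median of 25 genes (black). Inside the shaded stretch of 228 genes the median is 0.62, near the dashed line at the log2 of 3/2, and values beyond 3 are drawn at 3.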

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

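Unrounded counts, leaving out the stretch genes and removing the GC trend were chosen after the result was seen; the other alternatives were fixed before the data were examined. Over 15 alternatives without a minimum fold the genes called higher ranged from 2386 (DESeq2) to 3647 (upper-quartile factors), against 3427, and those called lower from 2543 (DESeq2) to 3652 (no low-count filter), against 3492. DESeq2 called 70.9% of the same genes, and every call shared with any of these alternatives had the same sign. A minimum log2 fold change of 1 left 703 higher and 1059 lower, by its own construction. Leaving out each library gave 2535 to 2922 higher and 2697 to 2919 lower, with fewer samples to set the spread. The replicate numbers were not shown to pair the libraries (correlation of the replicate differences across genes -0.05), and a replicate block gave 3050 higher and 3154 lower. Without the genes of the chromosome 1 and X stretches 3268 were higher and 3373 lower. Log2 fold changes fell with GC content across genes (Spearman -0.258, and genes are not independent replicates). Removing a trend that ranged from -0.10 to 0.30 left 3188 higher and 3350 lower, 84.0% of the main calls among them. The median log2 fold change of all genes was 0.0019, against 0.017 with upper-quartile factors.

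The log2 fold changes of TFAP2A, TFAP2B, TFAP2C and TFAP2E kept their sign and passed under all 15 alternatives without a minimum fold. Leaving out each library gave -0.65 to -0.44 for TFAP2A and -2.33 to -1.70 for TFAP2C. Of 94 named genes, 13 lost their call under at least 1 alternative and 0 changed sign. Of 200 called list members, 48 lost their call when some library was left out. With an estimated correlation each of the 9 list calls was lost: the adjusted p was 0.292 for surface ectoderm factors and for endothelium and blood, 0.437 for simple epithelium, 0.336 for desmosome, 0.39 for cell cycle, and 0.268 for neural crest, mesenchyme, amnion and trophoblast, and WNT response. The estimated correlation lay under the preset 0.01 for neural crest (-0.032) and for endothelium and blood (-0.139). This argues against correlation between genes as the reason for the loss of those calls. Why the calls were lost was not tested further. The desmosome list was also lost without the low-count filter (0.299) and with limma-voom (0.273), and the cause was not tested. Its other camera values passed. Fry, which asks only whether a list moves on balance, passed lists that camera did not, all downward: basal keratinocyte and hemidesmosome (0.0335), keratinocyte differentiation (0.00885), BMP response (0.0218), retinoic acid response (0.0141) and p53 and stress response (0.0335). The mitochondrial and ribosomal list ranged from 0.045 (without WT replicate 2) to 0.884 over the fits that left out a library. Every other list kept its side of the threshold. Thinning to the smallest library gave 3358 higher and 3422 lower, but the libraries differ little in depth, so this does not show whether depth limited the calls.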

Other observations

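All gene families in these opening paragraphs, and the tests on the extra copy, on position-independent effects, on WT cells, on TFAP2C, on deletions and on the X chromosome, were chosen after the result was seen. The tests on the constant shift, GC content and length, and depth were written before they were run, but for patterns already seen in these data. Of 22 families taken by gene symbol, 12 passed at the preset correlation (camera), 8 lower and 4 higher, and 0 passed with an estimated correlation. The Iroquois homeobox factors all fell, 6 of 6 (median log2 fold change -3.15; camera adjusted p = 5.27e-12, and adjusted p = 0.267 with an estimated correlation). IRX6 went from 16.9 to 0.297 CPM, IRX2 from 82.2 to 21.0 and IRX3 from 303 to 187. Of 35 collagen genes 23 fell and 7 rose (adjusted p = 1.03e-12, and 0.267 with an estimated correlation). COL11A2 fell from 254 to 18.2 CPM and COL6A6 from 118 to 12.3, whereas COL2A1, the cartilage collagen, rose from 447 to 1172 and the basement membrane genes COL4A1 and COL4A2 rose from 92.6 to 147 and from 218 to 400.3. Of 11 laminin genes 9 fell, among them LAMC1 from 925 to 478 CPM, and LAMA2 rose from 3.04 to 5.11, a call lost with DESeq2 (camera adjusted p = 1.3e-05, and 0.267 with an estimated correlation). WNT ligand genes fell in 8 of 12 cases (adjusted p = 0.000297, and 0.267 with an estimated correlation), with WNT11 from 7.07 to 0.194 CPM and WNT6 from 11.2 to 0.919. WNT5A rose from 36.7 to 127 CPM, and WNT2B was higher with an adjusted p of 0.0749 without knockout replicate 2. Of 5 DLX factors DLX2 (18.4 to 0.562 CPM), DLX3 and DLX5 fell (adjusted p = 0.000109, and 0.267 with an estimated correlation). Of 8 keratins KRT7, KRT8, KRT19 and KRT23 fell, while KRT222 was higher with an adjusted p of 0.207 without WT replicate 2 and lost its call in 7 of 15 alternatives (keratins, adjusted p = 0.00481, and 0.333 with an estimated correlation). Potassium channel genes, with the antisense gene KCNJ2-AS1 counted among them by its symbol, fell in 28 of 53 cases and rose in 10 (camera adjusted p = 0.00139, and 0.267 with an estimated correlation). Clustered protocadherins were lower in 38 of 53 cases (camera adjusted p = 0.00139, and 0.509 with an estimated correlation). Members of the alpha cluster, and those of the gamma cluster, share exons and so reads, which makes this count uncertain.

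Among the families that passed as higher, HOXD3 and HOXD4 rose, from 0.505 to 3.52 and from 0.847 to 4.51 CPM, and HOXD8, the other member tested, was higher with an adjusted p of 0.137 without knockout replicate 2 and was lost with DESeq2 too (HOXD cluster, adjusted p = 0.0356, and 0.333 with an estimated correlation). Of 9 frizzled receptor genes, which encode WNT receptors, 5 rose and 0 fell (adjusted p = 0.0289, and 0.282 with an estimated correlation). FZD2 rose from 113 to 202 CPM, FZD7 from 107 to 164 and FZD3 from 58.5 to 82.7, while FZD8 and FZD9 had adjusted p of 0.221 without knockout replicate 1 and 0.243 without WT replicate 1 and lost their calls in 3 and 6 of 15 alternatives. Of 10 FGF genes 5 rose and 2 fell (adjusted p = 0.0386, and 0.282 with an estimated correlation). FGF9 rose from 1.32 to 16.6 CPM, as did FGF5, FGF11 and FGF13, the last inside the X stretch, and FGF2 was higher with an adjusted p of 0.116 without knockout replicate 1, lost in 4 of 15 alternatives. FGF3 and FGF7 fell. Genes of neurofilaments and neuronal adhesion went both ways, with 9 of 17 higher and 6 lower (adjusted p = 0.00151, and 0.267 with an estimated correlation). NEFM rose from 1.13 to 35.4 CPM, NEFL from 1.30 to 27.4, the netrin receptor gene DCC from 0.958 to 19.2 and CNTN6 from 0.759 to 16.2, while NCAM2 fell from 160 to 87.8. The median of each family named here kept its sign under the RLE or upper-quartile factors.

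The chromosome 1 stretch held 228 genes at a median log2 fold change of 0.62 in the libraries labelled knockout. GC content and gene length are argued against, since 223 genes elsewhere matched on both and on level had a median of 0.055. Effects on genes irrespective of position are argued against too, because the scan score of 51.8 compared with at most 5.04 in 1000 shuffles of the gene order scanned in the same way. A candidate explanation is an extra copy in the cells labelled knockout: the 68 genes inside it that the scan had not used had a median of 0.41, with a 95% interval (Wilcoxon) of 0.15 to 0.62 that holds the log2 of 3/2, and the interquartile range of the scanned genes inside was 1.04 times that outside. DNA was not measured, the labels name no clones, and an effect of TFAP2A loss on the region as a whole stays open, untested.

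TFAP2A transcript in the libraries labelled knockout stood at 0.687 of its WT level. WT cells at such a share are argued against, because 52 of the 10354 genes with at least 10 CPM in WT lay under 10% of it in both libraries. A TFAP2C knockout under a TFAP2A label cannot be told apart from lower TFAP2C expression in a TFAP2A knockout: TFAP2C had a log2 fold change of -1.99 with counts left, TFAP2A itself fell, and an edit that keeps the transcript would be invisible in counts per gene. An edit of TFAP2A that leaves its mRNA stays open for the same reason.

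Some genes were near silent, at no more than 0.5 CPM, in both libraries of one genotype and at 5 CPM or more in both of the other, 18 in the libraries labelled knockout, such as THNSL2, C9orf64, PXMP4 and TLX3, and 8 in WT, such as PNOC, ZXDA and SYT11. At the level of the other genotype, at least 218 counts would have been found in the silent group. The limit of 5 CPM set such counts in advance, so this is no separate test of depth. For 17 of the genes near silent in the libraries labelled knockout, 33 neighbours had a median log2 fold change of -0.095. This argues against deletions reaching such neighbours as an explanation of the set, although 6 of the 17 had a neighbour at -1 or below. Neighbours were taken only from genes with a mean of at least 5 CPM that were not near silent themselves. A deletion whose adjoining genes were near silent or under that mean would be missed, so deletions in general were not excluded. For TNFSF8 a deletion cannot be told apart from lower expression, as the other 7 genes of its run on chromosome 9 (COL27A1 to ASTN2), all lower, had a median of -0.74. The scan had chosen this run for the low values of the same genes, so their fall is no separate evidence. For the genes near silent in WT, a different state of the X chromosome cannot be told apart from chance, as 1 of the 8 lay on X (odds ratio 3.89, 95% interval 0.0861 to 30.4, Fisher's exact test, two-sided p = 0.251). That test does not cover the higher and lower runs that the scan found on X. PNPLA4, also on X, reached 19.5 CPM in the libraries labelled knockout. It was left out only because WT replicate 2, at 0.51 CPM, lay just over the limit of 0.5 CPM. The count on X therefore depends on that limit. Differences in promoter silencing between clones and the loss of TFAP2A itself may both remain, untested.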
